A study of Hordeum vulgare with 22 samples.

How the data were processed

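RNA was extracted with TRIzol and a column kit from dissected barley inflorescences harvested around midday from plants in long days, treated to remove DNA and sequenced with Illumina libraries, per the labels. The series holds 22 samples, and 21 of them, in 6 groups of line and stage, have a column of counts that could be tied to a group. The column names give line and stage but not the library codes of the sample titles, so a replicate number only names a library and pairs nothing. One stage is headed W3.0 in the count columns and W3.5 in the labels and in the fold change columns of the authors' deposited table. The authors' log2 fold changes at W3.5 correlated across genes at r = 0.912 with those refitted from these count columns, while fold changes of another stage reached at most 0.499, and the columns were taken as W3.5. The library code prefix, 1327 or 1328, was read from the titles, where it is constant within each group. Of 42 per-sample columns of values, 21 were used and 21, the authors' log2 values per sample, were not.

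The deposited estimated counts come from Salmon, per the file headers, and need not be whole, and 94.8% of the values were not. The submitters' processing notes also name BWA 0.7.15, limma and GATK, without a role or order, and no version for Salmon. The genome build name is not given in the sources used here, while the annotation is credited to Mascher and colleagues per the file headers, and positions are printed as the table gives them. The log2 fold changes of the authors' deposited table, and its p-values and FDR values, are theirs, per the file headers. The authors' deposited table lists 262, 664 and 6396 genes at an FDR under 0.05 at W2.0, W3.5 and W5.0, of which 138, 591 and 5905 were also called in the refit. The table holds 1 transcript for each of 24318 genes, 1713 of them without position or annotation. Counts of 549 of these transcripts were identical to those of another transcript, 386 of them among the genes tested, so members of near-identical gene families share reads and their separate values are uncertain. Whether counting used strand is not given in the sources used here.

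Estimated counts were rounded to whole numbers, since the count model needs them. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21132 and removed 3186. Libraries were scaled by TMM, with factors from 0.902 to 1.08, and the median log2 fold change over all genes lay near 0 in every comparison. One model with a mean for each of the 6 groups was fitted to all 21 libraries with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood fit and F test. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05, and an adjusted p without another name is edgeR's. The 10 comparisons are mnd1.a against Bowman at each of 3 stages, the 3 interactions of line with stage, and 2 stage steps within each line. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled, and the prior count for log2 CPM was 0.25. Where a group had no counts, the fold is a lower bound against a floor of 3 counts summed over the group.

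The comparisons, the tests, the alternatives, the 27 gene lists and the rule for named genes were set before the data were examined. Lists were word patterns applied to the annotations. After the annotations were read, 6 lists received exclusions for wrong matches, and the lists without these are an alternative. Lists were tested at each stage with camera on signed z-scores of the edgeR p-values (limma 3.58.1, preset inter-gene correlation 0.01), adjusted over 78 tests. The change of the line difference between stages was tested in the same way for all 26 lists, 78 tests adjusted together, which was not among the planned tests and replaced tests of called lists only. Of 18 list calls, 2 held with an estimated correlation, photosynthesis at W2.0 and organelle-encoded products at W5.0. The median and mean log2 fold change of a list, and the direction of its test, had the same sign for all 18 called lists. Among lists without a call they differed in 16 tests, for example photosynthesis at W5.0 with a median of -0.25 and a mean of 0.01. Annotation families with at least 10 tested members were tested for enrichment per stage and direction by a one-sided hypergeometric test, 948 tests in all, against the 17015 tested genes with an informative annotation, each set of identical transcripts counted as 1. This family test was not among the planned ones. Positions were tested by Fisher's exact test per chromosome and over 460 windows of 10 Mb. The 7H segment from 620 to 660 Mb and the class of 83 ribosomal-RNA-like transcripts (annotated as senescence-associated proteins or rRNA intron-encoded homing endonucleases) were defined after the data were examined, as was the class of disease resistance genes.

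The named genes are MND1, a fixed set of flowering and spike genes whose annotation names the expected family, the 8 largest rises and 8 largest falls per stage among called genes with an annotation, a mean of at least 1 CPM and no overlap between the lines' libraries, and up to 4 members of each list with the smallest adjusted p. For stage steps and interactions the 5 largest each way were taken. Not all of these are printed. Genes printed outside the rule are marked as such.

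On simulated counts with known changes, the fit recovered 22.4%, 61.2% and 89.4% of genes changed 1.5-fold, 2-fold and 4-fold at W2.0 among 20747 genes tested, with 2.54% false calls. At W3.5 it recovered 22.4%, 67.2% and 78.8% among 20748 with 1.75% false calls, and at W5.0 37.3%, 55.2% and 80.3% among 20723 with 4.96%. In a simulation at W3.5 over 20727 genes, camera found the 1 shifted list and called 0 of 25 others. Simulated genes were drawn independently of each other, each around a common mean, with no prefix difference. Real lists had estimated correlations such as 0.669 for histone genes, so these rates do not measure the error in the real libraries.

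Alternatives were RLE scaling, no low-count filter, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01 with at least a 2-fold change, only the groups compared in the fit, and each library left out in turn. Added after seeing the data were calls outside the 7H segment, 1 gene per set of identical transcripts, calls without the 369 genes whose values separate the prefixes, a fit without Bowman W3.5 replicates 2 and 4, and an additive model of line, stage and prefix, whose prefix term rests on the W5.0 difference of the lines alone. A pseudocount alternative planned for normalized values did not apply to counts. The Mesa sample was not analysed here, and neither was FT1, for which no gene was used.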

Results

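Messenger RNA was sequenced from young inflorescences of 2 barley (Hordeum vulgare) lines, the spring cultivar Bowman and a line near-isogenic to it that carries the mnd1.a allele. Many-noded dwarf plants of barley are known for producing leaves at a fast rate and for an increased number of stem nodes, and the MND1 gene encodes an acyl-CoA N-acyltransferase. Tissue was taken at Waddington stages W2.0 (double ridges), W3.5 (stamen primordia) and W5.0 (later floret development), and each piece also held the base of the inflorescence and the small leaves under it. Bowman had 3 libraries at W2.0, 4 at W3.5 and 4 at W5.0, and mnd1.a had 3, 3 and 4. A further sample, shoot apices of cultivar Mesa at W1.0, was not analysed here. Total estimated counts per library lay between 11436651 and 21596190. The 10 most abundant transcripts of a library held 3.7% to 4.8% of its counts, and 3 counts, the floor used here for a value of 0, corresponded to 0.129 to 0.253 CPM (counts scaled to a common library size) in a single library. The floor covers counting error only. The labels do not say whether libraries came from separate plants, so p-values measure only the spread between these samples, which may be technical.

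The first principal component of log2 CPM held 37.6% of the variance and set the W2.0 libraries apart from the later ones, while W3.5 and W5.0 overlapped on it, and the second held 12.6%. The mnd1.a W5.0 libraries lay between 74.3 and 86.9 on the second component, and no other library lay above 11.2. The 4 Bowman W3.5 libraries were spread widely along the first component, at -10.8, 62.4, 17.5 and 105.2 for replicates 1 to 4, while the mnd1.a W3.5 libraries lay between -13.1 and -1.23 and the Bowman W5.0 libraries between 31.4 and 121.4. Correlations of log2 CPM between replicates ranged from 0.924 to 0.970, and no pair of libraries differed by less than sampling noise. The library codes in the sample titles start with 1327 or 1328. Both lines had prefix 1328 at W2.0 and 1327 at W3.5, but at W5.0 the mnd1.a libraries had 1328 and the Bowman libraries 1327, so that at W5.0 prefix and line cannot be told apart within the stage.

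**Figure D1:**
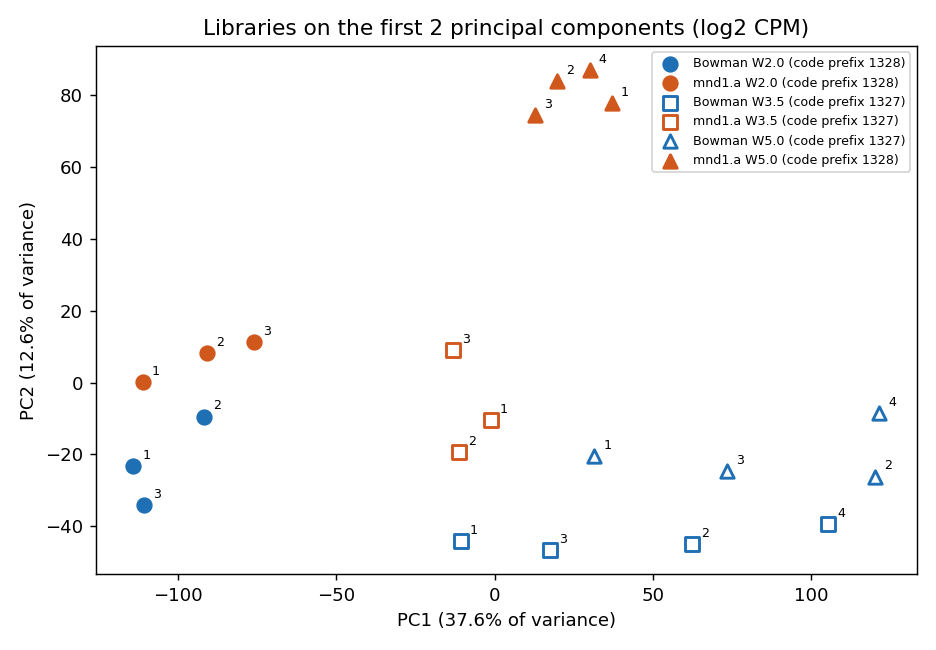
Each point is 1 of the 21 libraries on the first principal component of log2 CPM (37.6% of variance, x axis) and the second (12.6%, y axis), with the replicate number beside it, marker shape for stage and filled markers for library code prefix 1328. The W2.0 libraries of both lines lie at the left, and the 4 mnd1.a W5.0 libraries lie apart at the top.

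The first question was whether the MND1 transcript itself differed between the lines. MND1, HORVU7Hr1G113480, lies on 7H from 637080378 to 637082097 and was lower in mnd1.a at W3.5, at 4.05 ± 0.541 CPM (SD, n = 3) against 21.2 ± 7.55 CPM in Bowman (SD, n = 4), a log2 fold change of -2.38 ± 0.38 (SE, edgeR quasi-likelihood adjusted p = 0.00141). At W5.0 it was 5.08 ± 1.79 against 12.7 ± 4.60 CPM, a log2 fold change of -1.33 ± 0.33 (edgeR adjusted p = 0.00653). At W2.0 it was 5.58 ± 1.00 against 14.7 ± 5.55 CPM, and the log2 fold change of -1.40 ± 0.38 did not pass (edgeR adjusted p = 0.115). The size of the difference was not shown to depend on stage, with interaction adjusted p-values of 0.437, 0.369 and 0.954 from edgeR. No library, left out in turn, ended or made a call for MND1.

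At W2.0, photosynthesis transcripts were more abundant in mnd1.a than in Bowman. PsbS (HORVU3Hr1G082730), which dissipates excess light energy in photosystem II, measured 13.5 ± 4.60 CPM in mnd1.a and 3.64 ± 0.559 CPM in Bowman (SD, n = 3 each), a log2 fold change of 1.90 ± 0.25 (SE, edgeR adjusted p = 0.000481). Plastocyanin (HORVU7Hr1G000900), an electron carrier of the thylakoid, measured 24.6 ± 7.04 against 6.80 ± 1.05 CPM (log2 1.86 ± 0.26, edgeR adjusted p = 0.000835). PsbW (HORVU3Hr1G075870) rose by 1.45 ± 0.21 on the log2 scale and a small photosystem II protein (HORVU6Hr1G015770) by 1.81 ± 0.25. Of 89 tested members of the photosynthesis list, which was also fixed as a marker of green leaf tissue, 34 rose and 0 fell, or 54 and 0 adjusted over the list alone. The median log2 fold change was 1.26 (camera adjusted p = 8.96e-55, and adjusted p = 0.0107 with an estimated correlation). Chlorophyll a-b binding proteins, the light-harvesting antennae, were an enriched annotation family, with 6 of 17 higher. Ribosomal-RNA-like transcripts were lower in mnd1.a at this stage, with a median log2 fold change of -0.70, so a difference in library preparation stays open.

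Other lists at W2.0 had few called genes. Organelle-encoded products had a median of -0.66 over 10 tested members, 0 of them positive, with 0 called in either direction and list scores from -0.47 to 0.40 in mnd1.a libraries against 1.11 to 1.21 in Bowman (camera adjusted p = 0.00146, and 0.0561 as the adjusted p with an estimated correlation). Jasmonate and defence genes had a median of -0.28 over 105, with 0 rising and 1 falling, also adjusted over the list alone, and list scores from 0.92 to 1.02 against 1.45 to 1.81 (camera adjusted p = 3.28e-05, adjusted p = 0.641 with an estimated correlation, and 0.0651 with the list as first written). CONSTANS-like and B-box genes had a median of 0.21 over 23, with 1 rising and 0 falling, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.00269, and adjusted p = 0.166 with an estimated correlation). Ribosomal protein genes had a median of -0.10 over 310, with 1 rising and 1 falling, also adjusted over the list alone (camera adjusted p = 0.000506, adjusted p = 0.837 with an estimated correlation, and 0.823 without Bowman W2.0 replicate 2). The member that fell was 60S ribosomal protein L30 HORVU7Hr1G110660, at 67.1 ± 7.10 against 165 ± 18.1 CPM, and it fell also at W3.5 and W5.0, with log2 fold changes of -1.30, -1.39 and -1.22 at the 3 stages. This gene lies in the 7H segment around MND1, which may be donor chromosome. Its fall cannot therefore be ascribed to the allele.

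Some of the other genes with large differences at W2.0 were nearly silent in one line. A bZIP transcription factor gene (HORVU1Hr1G072090, 1H from 496009174 to 496009886) had no counts in Bowman and 5.70 ± 0.603 CPM in mnd1.a, at least 82.3-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 4.63e-06). A receptor-like protein kinase (HORVU7Hr1G107510) measured 26.6 ± 2.11 against 0.181 ± 0.135 CPM, a log2 fold change of 7.11 ± 0.58. A photosynthetic NDH subunit (HORVU2Hr1G042420) had a log2 fold change of 6.90 ± 0.60, a disease resistance protein (HORVU7Hr1G118440) 6.75 ± 0.54, the transcription factor bHLH130 (HORVU2Hr1G073240) 6.06 and ethylene-responsive transcription factor 5 (HORVU7Hr1G111280) 5.62. Lower in mnd1.a were organellar RNA editing factor MORF5 (HORVU2Hr1G040170), at 1.55 ± 0.357 against 19.1 ± 6.51 CPM (log2 -3.64 ± 0.43), a lysine-specific demethylase (HORVU2Hr1G045000, log2 -3.78 ± 0.60) and a second disease resistance protein (HORVU7Hr1G120020, log2 -3.57 ± 0.50). Each of these named genes passed with every library left out in turn. The kinase HORVU7Hr1G107510, HORVU7Hr1G111280 and both disease resistance genes lie in the 7H segment around MND1, which may be donor chromosome. Their differences cannot therefore be ascribed to the allele. The NDH subunit, MORF5 and the demethylase lie on 2H and changed the same way at all stages. Whether donor sequence is carried there was not tested, so their differences cannot be ascribed to the allele either. VRN-H1 (HORVU5Hr1G095630, log2 0.11) and PPD-H1 (HORVU2Hr1G013400, log2 0.07), regulators of flowering by cold and day length, did not pass (edgeR adjusted p of 0.943 and 0.951).

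In all, 167 of 21132 tested genes changed at W2.0, 105 higher and 62 lower in mnd1.a, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 135 changed at least 2-fold, and the libraries of the lines did not overlap in 167. Over all tested genes they did not overlap in 18.4%, where chance gives 10% for 3 against 3. The count was 111 without Bowman replicate 1, 108 without mnd1.a replicate 1 and 89 without mnd1.a replicate 3. An adjusted p under 0.01 with at least a 2-fold change left 71. The excess of higher genes depended on the method. DESeq2 called 325, 179 higher and 146 lower, and limma-voom 209, 90 higher and 119 lower. The authors' deposited table lists 262, 105 higher and 157 lower.

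At W3.5, some MADS-box transcription factor genes of flowering and floral development were lower in mnd1.a. MADS-box factor 34 (HORVU5Hr1G095710, 5H from 599329821 to 599336076), of the SEPALLATA group that acts in floral meristems, measured 0.872 ± 0.558 CPM in mnd1.a (SD, n = 3) against 27.8 ± 15.4 CPM in Bowman (SD, n = 4), a log2 fold change of -4.93 ± 0.74 (SE, edgeR adjusted p = 0.00105). VRN-H1 (HORVU5Hr1G095630, 5H from 599122941 to 599133084), a MADS-box promoter of the floral transition, measured 138 ± 10.2 against 271 ± 58.6 CPM (log2 -0.97 ± 0.18, edgeR adjusted p = 0.00452). Of 35 MADS-box genes tested, 12 fell and 0 rose, or 18 and 0 adjusted over the list alone, with a median of -0.997 (camera adjusted p = 3.00e-07, and adjusted p = 0.0915 with an estimated correlation). MADS6 (HORVU6Hr1G066140) had no counts in mnd1.a, at least 111-fold lower than the 7.71 ± 6.68 CPM of Bowman, but its adjusted p of 0.0244 from edgeR became 0.084 without mnd1.a replicate 1 and 0.085 without replicate 2. MADS5 (HORVU7Hr1G025700, log2 -4.79 ± 0.95, edgeR adjusted p = 0.0101) likewise lost its call without mnd1.a replicate 1 (0.064) or 2 (0.062).

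Growth-regulating factors, which promote cell proliferation in young organs, had 3 of 17 tested members lower and 0 higher, or 6 and 0 adjusted over the list alone, with a median of -0.32 (camera adjusted p = 4.69e-05, and adjusted p = 0.115 with an estimated correlation). GRF3 (HORVU0Hr1G016590) had a log2 fold change of -2.28 ± 0.40, and GRF4 (HORVU6Hr1G068370) fell from 45.6 ± 22.8 CPM in Bowman to 15.0 ± 1.79 CPM (log2 -1.59 ± 0.30). Squamosa promoter-binding-like genes, regulators of phase change, had 3 of 23 lower, among them SPL2 (HORVU2Hr1G097580, log2 -2.19 ± 0.33) and SPL17 (HORVU0Hr1G020810, log2 -1.03 ± 0.19). Homeobox genes had 3 of 78 higher and 8 lower. Neither the squamosa promoter-binding-like list nor the homeobox list had a call by camera at any stage (camera adjusted p of 0.233 and 0.458 at W3.5). The HD-Zip genes HORVU2Hr1G092300 (log2 -4.16 ± 0.76, edgeR adjusted p = 0.00456) and HORVU2Hr1G095210 (log2 -2.62 ± 0.46) fell, while homeobox-leucine zipper 3 (HORVU5Hr1G080700) rose by 1.07 ± 0.20. VRS1 (HORVU2Hr1G092290), the HD-Zip gene that controls the fertility of lateral spikelets, had a log2 fold change of -3.79 ± 0.79 (edgeR adjusted p = 0.0115, but 0.062 without mnd1.a replicate 1 and 0.077 without replicate 2).

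Hormone genes that passed at W3.5 included cytokinin oxidase 1 (HORVU1Hr1G057860), which degrades cytokinin, at 2.11 ± 0.450 against 0.441 ± 0.282 CPM (log2 2.19 ± 0.40, edgeR adjusted p = 0.00437). The auxin response repressors IAA2 (HORVU3Hr1G019750, log2 -0.97 ± 0.14) and IAA16 (HORVU1Hr1G028170, log2 -1.26 ± 0.24) fell. IAA2 was called lower also at W2.0 and W5.0 (log2 -0.76 and -0.48), so its fall was not particular to W3.5. Lipoxygenase 2 (HORVU6Hr1G000510), of the jasmonate pathway, rose by 6.40 ± 1.05. Cuticle and epidermis genes had 9 of 150 higher and 1 lower, or 15 and 2 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.000681, adjusted p = 0.648 with an estimated correlation, and 0.0636 without mnd1.a W3.5 replicate 3). They included 3-ketoacyl-CoA synthase 6 (HORVU7Hr1G042070), an enzyme of wax synthesis, with a log2 fold change of 2.55 ± 0.38. Vascular and wall genes had 2 of 88 higher and 2 lower, also adjusted over the list alone, with a median of 0.24, or 0.23 with genes at 0 set to their bound (camera adjusted p = 0.0174, and adjusted p = 0.812 with an estimated correlation). That call was lost without Bowman replicate 2 (0.0863) or 4 (0.217) or mnd1.a replicate 3 (0.164). Its higher members were a fasciclin-like protein (HORVU5Hr1G008960, log2 1.06 ± 0.17) and cinnamoyl-CoA reductase 1 (HORVU6Hr1G028980, log2 1.25 ± 0.25), which acts in lignin synthesis. Subtilisin-like proteases were an enriched annotation family, with 6 of 37 higher.

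Histone genes had a median of 0.41 at W3.5, with 4 of 177 higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 4.99e-12, and adjusted p = 0.735 with an estimated correlation). List scores were -0.31, -0.20, -1.20 and -0.12 in Bowman replicates 1 to 4 and -0.10 to 0.03 in mnd1.a, so that Bowman replicate 3 weighs heavily in this difference. The histone gene HORVU6Hr1G011030 went the other way, with a log2 fold change of -3.32 ± 0.40. Ribosomal protein genes had a median of 0.19, with 9 of 310 higher and 2 lower, or 4 and 2 adjusted over the list alone (camera adjusted p = 1.98e-11, and adjusted p = 0.648 with an estimated correlation). Ribosomal protein S3 (HORVU7Hr1G067280) measured 884 ± 179 against 432 ± 82.0 CPM (log2 1.03 ± 0.18). TCP transcription factors had a median of 0.39 with 0 of 18 called in either direction, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00197, and adjusted p = 0.550 with an estimated correlation). Photosynthesis genes had 0 of 89 called in either direction by edgeR over all genes, and organelle-encoded genes 0 of 10.

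In all, 826 genes changed at W3.5, 375 higher and 451 lower in mnd1.a (edgeR), and 348 of them at least 2-fold. The libraries of the lines did not overlap in 759 of them, and in 12.9% of all tested genes, where chance gives 5.71%. The count was 2273 without Bowman replicate 1, 481 without replicate 2 and 512 without replicate 4, and 303, 265 and 1350 without mnd1.a replicates 1, 2 and 3. It was 344 without Bowman replicates 2 and 4 together, the libraries nearest to W5.0 on the first component. With only the 2 groups in the fit it was 94, and 164 at an adjusted p under 0.01 with at least a 2-fold change. The main fit estimated the spread of a gene over all groups together. The median SD of log2 CPM between replicates was 0.265 in Bowman W3.5 and 0.142 to 0.215 in the other groups. Standard errors and adjusted p-values of comparisons with Bowman W3.5 may therefore be too small. The excess of lower genes also depended on the method. DESeq2 called 774 higher and 713 lower (1487 in all), limma-voom 363 and 289, and the authors' deposited table lists 372 and 292. Genes higher and lower were 1164 and 1109, 754 and 596, and 137 and 128 by edgeR without Bowman replicate 1, mnd1.a replicate 3 and mnd1.a replicate 2.

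**Figure D2:**
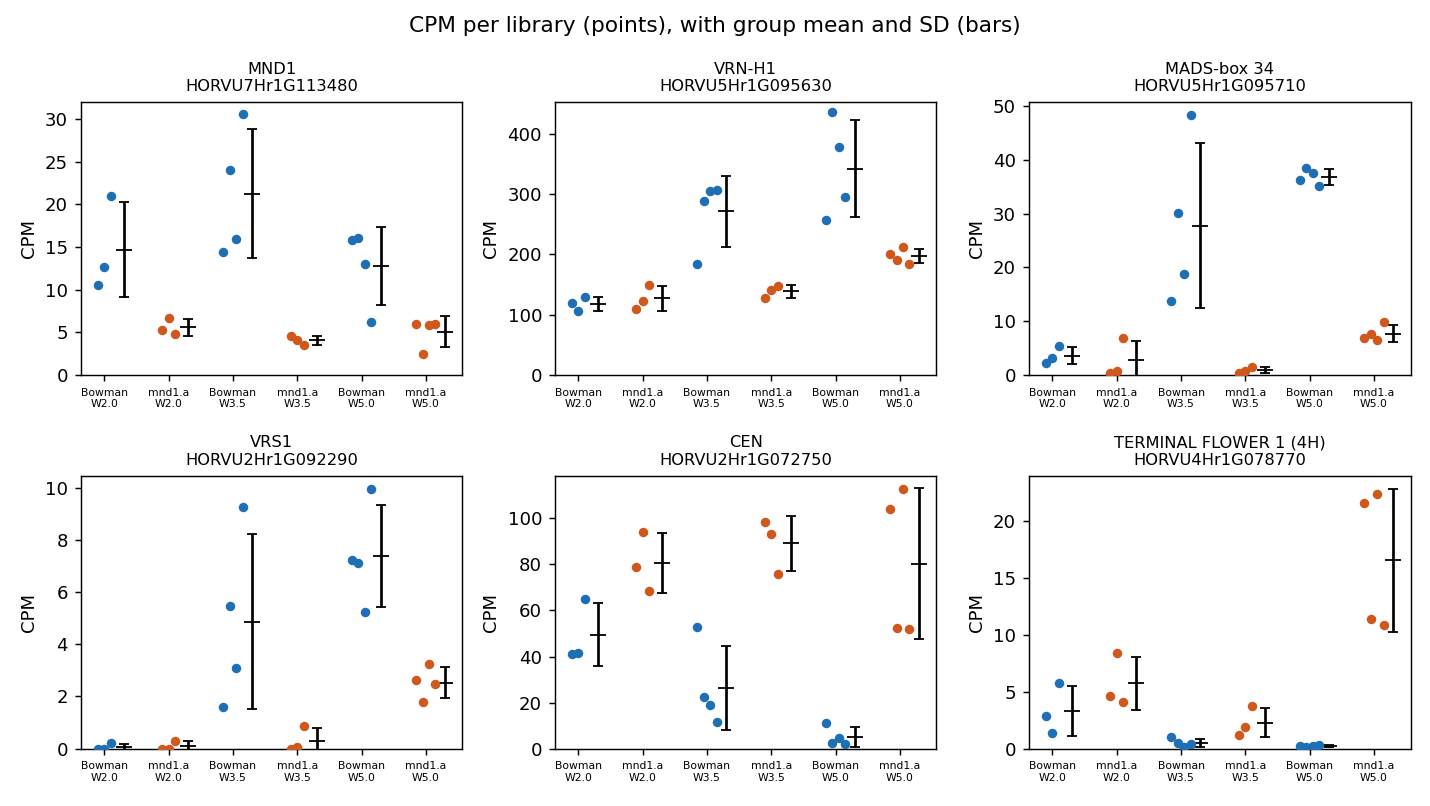
Points give CPM in each library for 6 genes (y axis) by line and stage (x axis), and bars give the group mean and SD. MND1, VRN-H1, MADS-box 34 and VRS1 lie lower in mnd1.a at W3.5, and CEN and the TERMINAL FLOWER 1 gene on 4H lie higher in mnd1.a at W5.0.

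At W5.0, homologs of TERMINAL FLOWER 1, which maintain inflorescence meristems and delay flowering, were far higher in mnd1.a. The copy on 4H (HORVU4Hr1G078770, from 609002595 to 609004185) measured 16.5 ± 6.31 CPM in mnd1.a against 0.223 ± 0.077 CPM in Bowman (SD, n = 4 each), a log2 fold change of 6.16 ± 0.57 (SE, edgeR adjusted p = 5.67e-07). CEN (HORVU2Hr1G072750, 2H from 523377523 to 523379139) measured 80.3 ± 32.7 against 5.03 ± 4.16 CPM (log2 3.94 ± 0.53, edgeR adjusted p = 7.37e-05), so that 2 of 3 tested members of its family rose, also adjusted over the list alone. The third, a PEBP gene (HORVU1Hr1G070690) printed outside the rule for named genes, had a log2 fold change of -3.07 ± 1.71 that did not pass (edgeR adjusted p = 0.186). The list had no call by camera (adjusted p = 0.0707). At W3.5 CEN had a log2 fold change of 1.75 ± 0.49 that did not pass (edgeR adjusted p = 0.0556, but 0.007 without Bowman W3.5 replicate 1). VRN-H1 (HORVU5Hr1G095630) was lower, at 197 ± 12 against 342 ± 80.5 CPM (log2 -0.80 ± 0.16, edgeR adjusted p = 0.00144), as was PPD-H1 (HORVU2Hr1G013400, 2H from 29123785 to 29127889), at 111 ± 7.89 against 156 ± 10.1 CPM (log2 -0.48 ± 0.10, edgeR adjusted p = 0.00212). MADS-box 34 (HORVU5Hr1G095710) measured 7.70 ± 1.57 against 36.9 ± 1.5 CPM (log2 -2.26 ± 0.51). Of 35 MADS-box genes 0 rose and 7 fell, or 0 and 6 adjusted over the list alone, and the list had no call by camera (adjusted p = 0.113).

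TCP transcription factors are the family of TEOSINTE BRANCHED 1, a gene that restrains branching. At W5.0 14 of 18 members rose and 0 fell, or 15 and 0 adjusted over the list alone. The median was 0.95 (camera adjusted p = 3.07e-07, and adjusted p = 0.0915 with an estimated correlation). INT-C (HORVU4Hr1G007040), whose annotation is TEOSINTE BRANCHED 1, did not pass at W5.0. The TEOSINTE BRANCHED 1-like gene HORVU5Hr1G000490 had a log2 fold change of 5.73 ± 0.77 at 1.16 CPM in mnd1.a, and TCP gene HORVU4Hr1G019380 measured 33.5 ± 5.23 against 17.0 ± 1.18 CPM (log2 0.98 ± 0.14). The mean log2 score of the TCP list was 0.37, 0.52 and 0.56 in the groups with prefix 1328 (Bowman W2.0, mnd1.a W2.0 and mnd1.a W5.0) and -0.54, 0.06 and -0.73 in those with 1327 (Bowman W3.5, mnd1.a W3.5 and Bowman W5.0), and TCP gene HORVU6Hr1G093960 separated the prefixes. Of 39 cytokinin genes 3 rose and 9 fell, and the list had no call by camera (adjusted p = 0.575). Among the named genes, response regulators ARR1 (HORVU2Hr1G062680, log2 -1.21 ± 0.16, edgeR adjusted p = 3.64e-05), ARR18 (HORVU5Hr1G018220, log2 -0.90) and ARR12 (HORVU6Hr1G085590, log2 -1.14) were lower, and cytokinin oxidase 1 (HORVU1Hr1G057860, log2 1.99 ± 0.36) was higher. Gibberellin receptors GID1 (HORVU7Hr1G057260, log2 1.05 ± 0.18) and GID1L2 (HORVU7Hr1G035800, log2 1.62 ± 0.38) were higher. Squamosa promoter-binding-like genes went both ways, with 6 of 23 higher and 7 lower, and SPL2 (HORVU2Hr1G097580, log2 -1.30) and SPL17 (HORVU0Hr1G020810, log2 -0.79) stayed lower. Homeobox-leucine zipper 3 (HORVU5Hr1G080700) was higher with a log2 fold change of 1.2, and GRF-interacting factor 3 (HORVU4Hr1G010610) lower with -0.58. Of 105 jasmonate and defence genes 22 rose and 9 fell, with a median of 0.27 and no call by camera. Jasmonate-induced proteins on 2H were among those that fell, HORVU2Hr1G014020 (from 30743962 to 30745532) from 766 ± 466 CPM in Bowman to 104 ± 25.3 CPM (log2 -2.88 ± 0.50, edgeR adjusted p = 0.000627) and HORVU2Hr1G013940 from 205 ± 140 to 10.8 ± 7.26 CPM (log2 -4.25 ± 0.75).

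Histone genes rose in 118 of 177 members at W5.0 and fell in 2, or 143 and 5 adjusted over the list alone, with a median of 0.71 (camera adjusted p = 2.62e-17, and adjusted p = 0.641 with an estimated correlation). H2A gene HORVU2Hr1G043860, a core histone, measured 315 CPM in mnd1.a and 152 CPM in Bowman (log2 1.05 ± 0.17). The mean log2 score of the histone list was 0.14, 0.15 and 0.47 in the groups with prefix 1328 (Bowman W2.0, mnd1.a W2.0 and mnd1.a W5.0) and -0.46, -0.03 and -0.20 in those with 1327 (Bowman W3.5, mnd1.a W3.5 and Bowman W5.0), and 12 histone genes separated the prefixes. Ribosomal protein genes rose in 137 of 310 and fell in 8, or 157 and 10 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 2.04e-12, and adjusted p = 0.641 with an estimated correlation). Cuticle and epidermis genes rose in 40 of 150 and fell in 2, or 39 and 2 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.000188, and adjusted p = 0.641 with an estimated correlation), among them a lipid-transfer protein (HORVU3Hr1G079800, log2 1.76 ± 0.20). Vascular and wall genes rose in 19 of 88 and fell in 1, or 17 and 1 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0262, and adjusted p = 0.812 with an estimated correlation), and that call was lost without Bowman replicate 2 (0.0732) or 4 (0.108) or mnd1.a replicate 3 (0.0947). Cinnamoyl-CoA reductase 1 (HORVU6Hr1G028980) was higher by 1.57 ± 0.23. Among sugar enzymes, a cell-wall invertase (HORVU2Hr1G109120), which splits sucrose, was lower (log2 -4.49 ± 0.51) and an acid invertase (HORVU7Hr1G001040) higher, at 686 against 80.6 CPM (log2 3.09 ± 0.50).

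Organelle-encoded products rose at W5.0 in 5 of 10 members and fell in 0, or 6 and 0 adjusted over the list alone, with a median of 1.98 (camera adjusted p = 0.000188, and adjusted p = 0.0162 with an estimated correlation). They included cytochrome c oxidase subunit 1 (HORVU7Hr1G020010, log2 2.25 ± 0.18) and maturase K (HORVU2Hr1G069650, log2 2.23 ± 0.23), and the values of both separated the libraries with prefix 1328 from those with 1327. Ribosomal-RNA-like transcripts moved with the same prefix. They took 1.24% to 2.71% of the counts in the 10 libraries with prefix 1328 and 0.213% to 0.369% in the 11 libraries with 1327, and 75 of 83 were higher in mnd1.a at W5.0, with a median log2 fold change of 3.20. At W2.0 and W3.5, where the lines share a prefix, 0 rose and 3 and 1 fell (edgeR), but at W2.0 the median log2 fold change was -0.70, and these transcripts took 1.24% to 1.55% of the counts in mnd1.a and 1.88% to 2.58% in Bowman. Photosynthesis genes rose in 11 of 89 and fell in 9, the largest changes among the named ones being in plastid-type PsaA (HORVU6Hr1G049190, log2 2.72 ± 0.31) and CP47 (HORVU6Hr1G049390, log2 1.84 ± 0.32), against a nuclear photosystem I subunit N (HORVU2Hr1G019820, log2 -1.32 ± 0.24).

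In all, 6381 genes changed at W5.0, 3170 higher and 3211 lower in mnd1.a (edgeR), and 1352 of them at least 2-fold with genes at 0 in one line set to their bound. The libraries did not overlap in 5549 of them, and in 34.2% of all tested genes, where chance gives 2.86%. An adjusted p under 0.01 with at least a 2-fold change left 895. Because line and prefix coincide at W5.0, line was also tested with stage and prefix as additive terms, which gave 458 genes for line. The prefix term had 933 genes, 896 of which were also changed in the comparison of lines at W5.0. In that model the prefix term rests on the W5.0 difference alone and the line term on W2.0 and W3.5, so it does not separate prefix from line at W5.0.

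**Figure D3:**
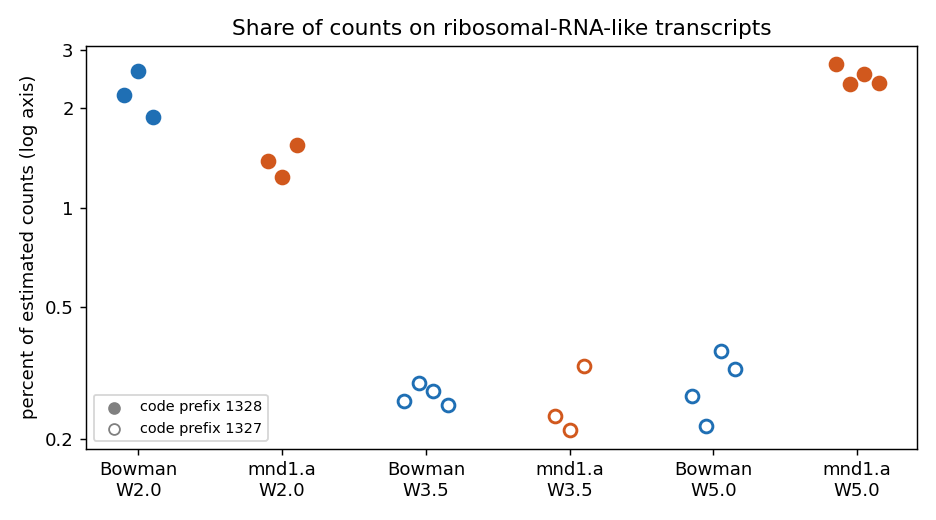
Each point is the percent of estimated counts on ribosomal-RNA-like transcripts in 1 library (y axis, log scale) by line and stage (x axis), filled for library code prefix 1328 and open for 1327. The libraries with 1328 lie between 1.24% and 2.71% and those with 1327 between 0.213% and 0.369%.

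The lists not described so far had no call by camera at any stage. In the order W2.0, W3.5 and W5.0 and as genes higher and lower, gibberellin genes (22 tested) had 0 and 0, 2 and 0, and 5 and 1. Cytokinin genes (39) had 0 and 1, 1 and 1, and 3 and 9, auxin genes (125) had 1 and 1, 0 and 6, and 16 and 15, and abscisic acid and dehydration genes (68) had 0 and 0, 0 and 1, and 7 and 3. AP2 and ethylene response factors (74) had 1 and 0, 1 and 4, and 7 and 6, and circadian clock genes (11) had 0 and 0, 0 and 1, and 0 and 3. Acyltransferases of the MND1 family (32), MND1 included, had 0 and 0, 0 and 1, and 3 and 9, and sugar metabolism genes (116) had 0 and 1, 1 and 3, and 15 and 17. Expansins and related growth genes (56) had 0 and 0, 0 and 0, and 9 and 1, and heat shock proteins (197), fixed as a marker of handling stress, had 0 and 0, 3 and 4, and 31 and 33. Cell cycle genes (127) had 0 and 0, 0 and 0, and 9 and 12, and anther and meiosis genes (19) had 0 and 0, 1 and 0, and 3 and 4. Vascular and wall genes, cuticle and epidermis genes, histone genes, TCP genes, growth-regulating factors and squamosa promoter-binding-like genes had 0 and 0 at W2.0, MADS-box genes 0 and 1, homeobox genes 0 and 0 at W2.0 and 15 and 9 at W5.0, and the TERMINAL FLOWER 1 family 0 and 0 at W2.0 and 1 and 0 at W3.5. That 1 gene (HORVU4Hr1G078770, edgeR adjusted p = 0.0448) lost its call without Bowman W3.5 replicate 2 (0.0950), 3 (0.115) or 4 (0.0960) or mnd1.a W3.5 replicate 1 (0.0506), 2 (0.0996) or 3 (0.154). CONSTANS-like genes had 0 and 0 at W3.5 and 1 and 5 at W5.0, jasmonate and defence genes 3 and 0 and 22 and 9, and growth-regulating factors 2 and 4 at W5.0. No annotation of a tested gene matched the list of CYP78A plastochron regulators. MND6 (HORVU5Hr1G081060), a CYP78A gene annotated as a cytochrome P450, had log2 fold changes of 0.87, -1.06 and -0.74 that did not pass (edgeR adjusted p of 0.508, 0.110 and 0.101, but 0.0163 at W3.5 without Bowman W3.5 replicate 1).

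The position of the changed genes was compared because the lines are near-isogenic. Genes on 7H were changed more often than elsewhere at W2.0 (odds ratio 2.02, adjusted p = 0.00289 by Fisher's exact test) and W3.5 (1.59, adjusted p = 3.43e-05), but not detectably at W5.0 (1.06, adjusted p = 0.5). At W5.0 genes on 4H were changed more often (1.16, adjusted p = 0.0160) and genes on 3H less often (0.842, adjusted p = 0.00141), by Fisher's exact test. In windows of 10 Mb, the excess at W2.0 and W3.5 lay around MND1 in the 3 windows starting at 620, 630 and 640 Mb. At W5.0 the window at 630 Mb passed on 7H, with 44 of 86 genes changed, beside windows on 5H (from 0 Mb, 38 of 73), 6H (from 10 Mb, 52 of 114), 1H (from 130 Mb, 17 of 27) and 2H (from 100 Mb, 20 of 34). From 620 to 660 Mb, 33, 80 and 158 of 378 tested genes changed at W2.0, W3.5 and W5.0, or 8.73%, 21.2% and 41.8%, against 0.646%, 3.59% and 30% of the genes elsewhere. These bounds were set after the windows were seen. Disease resistance genes, which include receptors of pathogen effectors and were picked as a class after the changed genes were seen, changed more often than the other genes of this segment, 7, 12 and 19 of 26 against 26, 68 and 139 of 352 (unadjusted p = 0.00402, 0.00437 and 0.00148 by Fisher's exact test), and elsewhere 0, 4 and 61 of 242 changed by edgeR. A window of 2H from 200 to 210 Mb was also enriched at W2.0 and W3.5, with 4 and 7 of 27 genes changed, and a window of 5H from 210 to 220 Mb at W2.0, with 3 of 9.

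**Figure D4:**
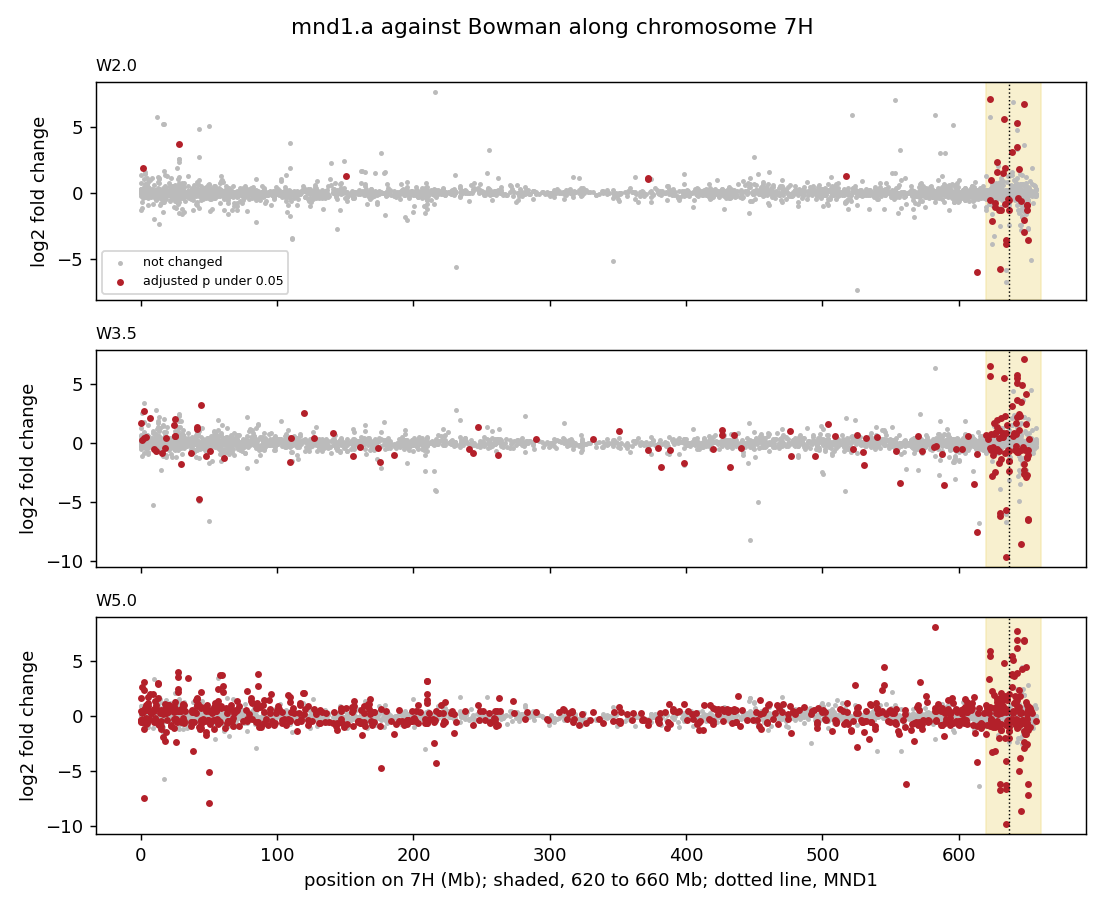
The log2 fold change of mnd1.a against Bowman (y axis) for each tested gene along 7H (x axis, Mb) at the 3 stages, with genes at an edgeR adjusted p under 0.05 in red, the segment from 620 to 660 Mb shaded and the position of MND1 dotted. At W2.0 and W3.5 the changed genes crowd into the segment, where 33 and 80 of 378 changed.

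Changed genes were compared between stages. Between W3.5 and W5.0, 301 genes were higher at both and 306 lower at both, where independent lists would share 56.3 and 68.5, and 3 and 1 went in opposite directions. Between W2.0 and W3.5, 26 and 44 were shared (1.86 and 1.32 for independent lists). Between W2.0 and W5.0, 47 lower genes were shared (9.42 for independent lists) and 4 were opposite, but of 105 genes higher at W2.0, 25 were shared (15.8) and 24 were lower at W5.0. Outside the 7H segment 15 of 93 higher genes were shared (13.8) and 24 were opposite. At all 3 stages 67 genes changed, 66 of them in the same direction, 23 higher and 43 lower, and 29 of the 66 lay in the 7H segment. Among the others were the bZIP gene HORVU1Hr1G072090, at least 82.3-fold, 90.9-fold and 96.1-fold higher at W2.0, W3.5 and W5.0, MORF5 (HORVU2Hr1G040170) with log2 fold changes of -3.64, -3.41 and -4.09, and the lysine-specific demethylase gene (HORVU2Hr1G045000) with -3.78, -4.57 and -3.21. Chosen after their values were seen, chalcone isomerase (HORVU2Hr1G038260), an enzyme of flavonoid synthesis, had 0.81, 1.06 and 1.29, and histidine kinase 5 (HORVU2Hr1G106760) had -1.05, -1.06 and -2.09. No leave-out was run for these last genes, for MORF5 at W3.5 and W5.0 or for the demethylase at W5.0. Of the 37 genes outside the 7H segment that changed the same way at all stages, 18 lay on 2H. MORF5, the demethylase, chalcone isomerase and the NDH subunit HORVU2Hr1G042420 start there at 194460899, 235343289, 179217892 and 212924544, on either side of the enriched window from 200 to 210 Mb. Whether donor sequence is carried there as well was not tested, so these differences cannot be ascribed to the allele.

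Whether the difference between lines changed with stage was tested directly. From W2.0 to W3.5, the transcription factor HY5 (HORVU6Hr1G037760), which promotes light responses, moved down in mnd1.a relative to Bowman by -2.97 ± 0.47 (SE, edgeR adjusted p = 0.00963), and a sulfite reductase (HORVU1Hr1G065770), of sulfate assimilation, moved up by 1.57 ± 0.22 (edgeR adjusted p = 0.00671). The photosynthesis list moved down with a median of -1.38 (camera adjusted p = 2.18e-31) and the MADS-box list with -1.34 (camera adjusted p = 1.93e-07), but neither passed with an estimated correlation (adjusted p = 0.0955 for each). Ribosomal protein genes moved up with 0.28 (camera adjusted p = 1.18e-15) and histone genes with 0.47 (camera adjusted p = 1.50e-09). Jasmonate and defence, TCP and organelle-encoded lists also moved up, and clock genes and growth-regulating factors down. None of these passed with an estimated correlation either. In all 40 genes changed, 12 up and 28 down. That count was 13 and 85 without Bowman W2.0 replicates 2 and 3, 206, 24 and 22 without Bowman W3.5 replicates 1, 2 and 3, 21 and 10 without mnd1.a W2.0 replicates 1 and 3, and 16, 13 and 501 without mnd1.a W3.5 replicates 1, 2 and 3.

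From W3.5 to W5.0, the cell-wall invertase HORVU2Hr1G109120 moved down by -4.47 ± 0.69 (SE, edgeR adjusted p = 0.00123). Organelle-encoded products moved up with a median of 1.54 (camera adjusted p = 0.000100, and adjusted p = 0.0103 with an estimated correlation). The MADS-box list moved up with 0.33 (camera adjusted p = 0.00571) and TCP genes with 0.58 (camera adjusted p = 0.000121). Histone, ribosomal protein, growth-regulating factor, TERMINAL FLOWER 1 family and AP2 lists also moved up. None of these other lists passed with an estimated correlation. On this step the prefix changed in mnd1.a alone. In all 215 genes changed, 155 up and 60 down, or 136 without mnd1.a W3.5 replicate 2, and 90 without the genes whose values separate the prefixes. Separation requires that the lines do not overlap at W5.0, and 362 of these 369 genes changed there, so that drop follows by construction. From W2.0 to W5.0, CEN (HORVU2Hr1G072750) moved up by 3.23 ± 0.73 (edgeR adjusted p = 0.0120), VRN-H1 (HORVU5Hr1G095630) down by -0.90 ± 0.25 (0.0267) and PPD-H1 (HORVU2Hr1G013400) down by -0.55 ± 0.16 (0.0343), and a cytochrome P450 (HORVU1Hr1G007790) up by 5.95 ± 1.23 (0.00728). The VRN-H1 call was lost without Bowman W2.0 replicate 1 (0.0574) or 2 (0.0812), Bowman W5.0 replicate 2 (0.0520) or 3 (0.0501), mnd1.a W2.0 replicate 3 (0.0872) or mnd1.a W5.0 replicate 4 (0.0521). The PPD-H1 call was lost, at 0.0525 to 0.0848, without Bowman W2.0 replicate 1 or 2, Bowman W5.0 replicate 3 or 4, any mnd1.a W2.0 replicate or mnd1.a W5.0 replicate 2, 3 or 4.

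From W2.0 to W5.0 the photosynthesis list moved down with a median of -1.72 (camera adjusted p = 2.29e-18, and adjusted p = 0.2 with an estimated correlation). Ribosomal protein genes moved up with 0.38, histone genes with 0.76 and TCP genes with 1.05 (camera adjusted p of 1.45e-15, 6.10e-15 and 2.31e-06). Jasmonate and defence and cuticle lists also moved up, and MADS-box, CONSTANS-like and clock lists down. None of these passed with an estimated correlation. Organelle-encoded products moved up with 2.88 (camera adjusted p = 6.47e-07, and adjusted p = 0.000443 with an estimated correlation). The prefix changes on this step in Bowman alone. A prefix effect and an interaction cannot be told apart for these lists, for CEN, VRN-H1 and PPD-H1 or for the count of genes. In all 2172 genes changed, 1075 up and 1097 down. That count was 1194 and 930 without Bowman W2.0 replicates 1 and 2, 1212 and 967 without mnd1.a W2.0 replicates 2 and 3, and 1354 without mnd1.a W5.0 replicate 4.

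Within Bowman, the step from W2.0 to W3.5 brought floral MADS-box genes on and defence genes down. MADS6 (HORVU6Hr1G066140) and MADS7 (HORVU7Hr1G054220), which act in floral organs, rose from no counts to 7.71 and 7.79 CPM, at least 111-fold and 113-fold higher (edgeR adjusted p of 0.00463 and 0.00434), and a thaumatin-type pathogenesis-related protein (HORVU5Hr1G005180) fell from 12.9 CPM to no counts, at least 270-fold lower (edgeR adjusted p = 2.75e-05). MADS-box genes rose in 18 of 35 and fell in 2, jasmonate and defence genes rose in 4 of 105 and fell in 43, photosynthesis genes rose in 64 of 89 and fell in 4, and histone genes rose in 3 of 177 and fell in 83. TCP genes fell in 11 of 18 and rose in 0. In all 6210 genes changed, 3006 up and 3204 down (edgeR), a step on which the prefix changed as well. The count was 4108 and 4042 without Bowman W2.0 replicates 1 and 2.

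From W3.5 to W5.0, both with prefix 1327, 1604 genes changed in Bowman, 822 up and 782 down, and CEN (HORVU2Hr1G072750) fell with a log2 fold change of -2.34 ± 0.51 (edgeR adjusted p = 0.0209). A polyamine oxidase (HORVU4Hr1G071450) rose by 5.76 ± 1.21 (edgeR adjusted p = 0.0204), and ribosomal protein genes rose in 0 of 310 and fell in 37. Both named calls were lost without Bowman W3.5 replicate 1 (0.0826 for CEN and 0.0746 for the oxidase), Bowman W5.0 replicate 2 (0.0859 and 0.0699) or 4 (0.0570 and 0.0534). The count of genes was 36, 813 and 3523 without Bowman W3.5 replicates 1, 2 and 4 and 3263, 29, 547 and 136 without Bowman W5.0 replicates 1 to 4. With only these 2 groups in the fit edgeR called 0 genes, with 3413 at an unadjusted p under 0.05, while DESeq2 over all groups called 2572 and limma-voom 1654.

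In mnd1.a, the step from W2.0 to W3.5 changed 799 genes, 336 up and 463 down (edgeR), again with a change of prefix. The MADS-box list had 1 of 35 up and 2 down, and photosynthesis genes 0 of 89 up and 2 down. Meiosis 5 (HORVU7Hr1G088880) fell from 13.2 to 0.125 CPM (log2 -6.50 ± 0.90, edgeR adjusted p = 0.000786). The count was 266, 363 and 340 without mnd1.a W2.0 replicates 1, 2 and 3 and 269 and 347 without mnd1.a W3.5 replicates 1 and 2.

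From W3.5 to W5.0 in mnd1.a, MADS6 (HORVU6Hr1G066140) rose from no counts to 18.7 ± 3.55 CPM, at least 268-fold (edgeR adjusted p = 0.00363), and MADS7 (HORVU7Hr1G054220) by 6.25 ± 1.08 on the log2 scale. MADS-box genes rose in 15 of 35 and fell in 3, homeobox genes rose in 20 of 78 and fell in 2, and squamosa promoter-binding-like genes rose in 7 of 23. An enzyme of ethylene synthesis, ACC oxidase (HORVU7Hr1G116830), fell from 18.7 to 0.533 CPM (log2 -5.10 ± 0.61, edgeR adjusted p = 3.38e-05). In all 2140 genes changed, 1082 up and 1058 down, once more with a change of prefix. The count was 925 and 796 without mnd1.a W3.5 replicates 1 and 2 and 1313 and 1157 without mnd1.a W5.0 replicates 2 and 4.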

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

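The tests of library code prefix, developmental delay or advance, donor segment and lost reads below were chosen after the results were seen, and the regroupings of the libraries were planned.

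Between stages, the difference of mnd1.a from Bowman changed for 40 genes from W2.0 to W3.5, 215 from W3.5 to W5.0 and 2172 from W2.0 to W5.0, by interaction tests in edgeR. From W2.0 to W3.5 the log2 interaction was 4.36 for an Hfr-2-like gene (HORVU5Hr1G102530), 2.94 for a phosphoadenosine phosphosulfate reductase (HORVU0Hr1G003890), 2.00 for a tetratricopeptide gene (HORVU1Hr1G075210), and 1.57 and 1.36 for sulfite reductases (HORVU1Hr1G065770 and HORVU0Hr1G026700). It was -9.63 for MADS5 (HORVU7Hr1G025700), -5.48 for a SINA-like ubiquitin ligase (HORVU3Hr1G018420), -3.96 for flowering promoting factor 1 (HORVU2Hr1G007350), -3.60 for an aldolase (HORVU5Hr1G032980) and -2.97 for HY5 (HORVU6Hr1G037760). HY5 and sulfite reductase HORVU1Hr1G065770 kept the call with each library left out, and the other 8 lost it in 5 to 10 of the leave-outs, with the highest edgeR adjusted p without mnd1.a W2.0 replicate 3 for each (from 0.109 for HORVU5Hr1G102530 to 0.308 for MADS5).

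From W3.5 to W5.0 the interaction was 5.60 and 4.73 for senescence-associated, ribosomal-RNA-like transcripts (HORVU0Hr1G024170 and HORVU7Hr1G030010), 4.52 for cytochrome b (HORVU3Hr1G040840), 4.22 for ATP synthase subunit 9 (HORVU7Hr1G089590) and 4.21 for the SINA-like ligase (HORVU3Hr1G018420). It was -6.65 for ribosomal protein L14 (HORVU2Hr1G089090), -4.47 for a cell-wall invertase (HORVU2Hr1G109120), -3.71 for an SKP1-like gene (HORVU6Hr1G000660), -3.67 for a carnitine transporter (HORVU0Hr1G003480) and -3.39 for a dihydroflavonol reductase-like gene (HORVU5Hr1G023460). The call was lost for cytochrome b (highest edgeR adjusted p 0.0906, without Bowman W3.5 replicate 3), ATP synthase subunit 9 (0.130, the same library), the SINA-like ligase (0.117, without mnd1.a W3.5 replicate 1) and the carnitine transporter (0.0632, without mnd1.a W5.0 replicate 4), each also without other libraries, and the other 6 kept it. The prefix changes on this step in mnd1.a alone, and both senescence-associated transcripts, cytochrome b, ATP synthase subunit 9, L14 and the SKP1-like gene separated the prefixes, so that for them a prefix effect and an interaction cannot be told apart.

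From W2.0 to W5.0 it was 7.09 and 5.95 for cytochromes P450 (HORVU1Hr1G007900 and HORVU1Hr1G007790), 6.44 for an alcohol dehydrogenase (HORVU1Hr1G007800), 5.47 each for protochlorophyllide reductase A (HORVU2Hr1G119050) and a cathepsin B-like protease (HORVU7Hr1G120060), and 3.23 for CEN (HORVU2Hr1G072750). It was -9.32 for a hexosyltransferase (HORVU0Hr1G000650), -7.67 for a transcription elongation factor (HORVU6Hr1G010530), -6.58 for L14 (HORVU2Hr1G089090), -6.02 for MADS5 (HORVU7Hr1G025700), -5.81 for a disease resistance gene (HORVU7Hr1G117570), -0.90 for VRN-H1 (HORVU5Hr1G095630) and -0.55 for PPD-H1 (HORVU2Hr1G013400). CEN, cytochrome P450 HORVU1Hr1G007790 and the hexosyltransferase kept the call with each library left out. It was lost without Bowman W2.0 replicate 2 for HORVU1Hr1G007900 (edgeR adjusted p = 0.732), the alcohol dehydrogenase (0.0732), protochlorophyllide reductase A (0.0504), the protease (0.0885) and PPD-H1 (0.0848), without mnd1.a W2.0 replicate 3 for the elongation factor (0.204), MADS5 (0.253), the resistance gene (0.0656) and VRN-H1 (0.0872), and without mnd1.a W2.0 replicate 2 for L14 (0.0875). Apart from the dehydrogenase, the reductase and L14, these lost it without other libraries as well. On this step the prefix changes in Bowman alone, so that a prefix effect and an interaction cannot be told apart. Of these genes L14 separated the prefixes. By their gene numbers the resistance gene and the protease fall among or beside genes of the 7H segment, which may be donor chromosome. Their values cannot therefore be ascribed to the allele. Fitted values of genes with no counts in a group depend on the prior count and are not bounds. Over interaction tests of all 26 lists, the median of organelle-encoded products differed from W3.5 to W5.0 (1.54) and from W2.0 to W5.0 (2.88) by camera with an estimated correlation (adjusted p of 0.0103 and 0.000443).

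Single libraries stood apart from the other 3 of their group of 4 by Dixon's criterion in 19 cases, from 138 checks of genes and 84 of lists and library measures, where chance marks about 1 in 20 groups. As log2 CPM, MND1 (HORVU7Hr1G113480) was 1.27 in mnd1.a W5.0 replicate 2 (others from 2.57 to 2.59), and VRN-H1 (HORVU5Hr1G095630) was 7.52 in Bowman W3.5 replicate 1 (others from 8.17 to 8.26). In mnd1.a W5.0, the NDH subunit HORVU2Hr1G042420 was 2.09 in replicate 2, the resistance gene HORVU7Hr1G118440 was 2.86 and the epimerase HORVU3Hr1G067020 -5.90 in replicate 3, and HORVU2Hr1G053350 was -2.46 and NF-YB6 (HORVU6Hr1G072110) 2.85 in replicate 1. In Bowman W5.0 replicate 3, chlorophyll a-b binding protein HORVU1Hr1G078380 was 2.59 and alcohol dehydrogenase HORVU1Hr1G007800 -1.50. In Bowman W3.5, bHLH130 (HORVU2Hr1G073240) was -3.63 in replicate 1, HORVU5Hr1G042570 -2.45 in replicate 2 and the resistance gene HORVU7Hr1G120020 6.08 in replicate 3. The mean log2 value of ribosomal-RNA-like transcripts was -0.88 in Bowman W5.0 replicate 3 (others from -1.43 to -1.39), and that of cuticle genes was -0.39 in mnd1.a W5.0 replicate 1 (others from 0.01 to 0.08). List means also stood apart for abscisic acid and dehydration genes (-0.47, the same library), clock genes (-0.062, mnd1.a W5.0 replicate 3), homeobox genes (0.29, Bowman W5.0 replicate 1), acyltransferases of the MND1 family (0.18, Bowman W5.0 replicate 3) and cell cycle genes (-0.33, Bowman W3.5 replicate 3).

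The first pattern weighed is the large count at W5.0. The prefix as its whole cause is argued against by W3.5, where both lines have prefix 1327. Genes changed at W5.0 outside the 7H segment were shifted in the W5.0 direction by a median of 0.234 there, and the highest of the other splits of the W3.5 libraries, 35 with the real one, gave 0.205, a narrow margin. For ribosomal-RNA-like transcripts the prefix remains a candidate explanation, since all 10 libraries with 1328 lay above every library with 1327. A lag of mnd1.a behind Bowman in development stays open: genes that change in Bowman from W2.0 to W5.0 were shifted against that direction by a median of -0.192 at W3.5, but another split gave -0.234.

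The second pattern is the rise of photosynthesis genes at W2.0. An advance of mnd1.a W2.0 libraries in development was predicted to take other genes along the Bowman change from W2.0 to W3.5 as well. Those that changed one way over both Bowman steps, 532 genes, covered a median of 0.135 of it (0.0814 to 0.230 with libraries left out). Photosynthesis genes covered 0.757 (0.643 to 0.831). As that step also changes prefix, the fraction was taken of the difference of mnd1.a W5.0 from Bowman W2.0, both with 1328. There 414 other genes covered 0.157 (0.0791 to 0.223) and 59 photosynthesis genes 0.762 (0.640 to 0.858). Both results argue against an advance by a like part for all these genes. They do not decide on an advance as such. The other genes had to keep changing after W3.5, while photosynthesis genes only had to rise by W3.5. From W3.5 to W5.0 in Bowman, 1 of 89 photosynthesis genes rose and 1 fell. Genes that level off early can cover more of a step at the same advance, so an advance stays open. A larger share of green leaf tissue in the mnd1.a pieces may account for the rise and stays open with an effect of the allele itself: at W2.0 the lists fixed as markers of vascular tissue and epidermis had 0 of 88 and 0 of 150 genes called (edgeR) and medians of 0.09 and 0.10 against 1.26 for photosynthesis genes, but their level in the inflorescence itself could hide a small share of leaf. A difference in library preparation also stays open, since ribosomal-RNA-like transcripts were lower in mnd1.a at W2.0 (median log2 -0.70).

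The third pattern is the cluster on 7H. A segment of donor chromosome carried along with the allele may account for it: of 33 segment genes changed at W2.0, 29 changed the same way at all stages, but the bounds came from windows of these stages. With bounds from the W2.0 windows alone, 620 to 650 Mb, 26 of 30 genes changed at W2.0 did so, against 40 of 137 elsewhere (p = 6.3e-09, Fisher's exact test). Loss of mnd1.a reads on alleles unlike the reference as the whole cause is argued against by the 40 segment genes higher and 40 lower at W3.5. Loss of reads of either line for part of the genes, and effects of the allele on its neighbours, stay open.

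Regrouping the libraries tested whether the counts could be chance. Among comparisons with 35 or 40 splits, only the real one reached its count at W5.0 (6381 genes, highest other split 2) and for the W2.0 to W5.0 interaction (2172, highest other 38). The same held for the steps in mnd1.a from W3.5 to W5.0 (2140, highest other 4) and, by a narrow margin, in Bowman from W2.0 to W3.5 (6210, highest other 5945). This argues against chance there but does not exclude it. A share of 1 in 35 or 40 is the lowest possible, and the shares were not adjusted over the 10 comparisons. Splits for the interactions exchanged lines within a stage, which also breaks up a line difference, so they do not test the interaction alone. Chance is not argued against at W3.5 (826 genes, highest other 2331, 2 of 35 splits as large), for the interactions from W2.0 to W3.5 (40, highest other 555, 5 of 40) and W3.5 to W5.0 (215, highest other 1323, 3 of 40), or in Bowman from W3.5 to W5.0 (1604, highest other 3455, 2 of 35). The larger splits point to a structure of the samples: at W3.5 the largest moved Bowman replicate 1 to the mnd1.a side, and in Bowman it exchanged W3.5 replicate 4 with W5.0 replicate 1. For W2.0 (167, highest other 15) and mnd1.a from W2.0 to W3.5 (799, highest other 0) the 10 splits are too few for a share under 0.05.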

How the results depend on the processing

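The alternatives that leave out Bowman W3.5 replicates 2 and 4, drop prefix-separating or 7H genes, drop the list exclusions or add a prefix term were chosen after the results were seen. No paired analysis was possible because the labels name no pairing of libraries, and the replicate numbers of the count columns are not tied to the library codes of the labels. Counts of changed genes by RLE scaling, without the low-count filter and with 1 gene per set of identical transcripts stayed within 1.5 times in all 10 comparisons. In the order W2.0, W3.5, W5.0, the interactions W2.0 to W3.5, W3.5 to W5.0 and W2.0 to W5.0, Bowman W2.0 to W3.5 and W3.5 to W5.0, and mnd1.a W2.0 to W3.5 and W3.5 to W5.0, an adjusted p under 0.01 with at least a 2-fold change gave 71, 164, 895, 9, 103, 325, 1258, 3, 151 and 467 genes. DESeq2 moved W2.0 to 325, W3.5 to 1487, the first 2 interactions to 370 and 483, Bowman W3.5 to W5.0 to 2572 and mnd1.a W2.0 to W3.5 to 1308. Limma-voom gave 23 for the first interaction, and its split of higher and lower genes was 90 and 119 at W2.0 (105 and 62 in edgeR) and 363 and 289 at W3.5 (375 and 451). With only the groups compared in the fit, W3.5 had 94 genes, the W2.0 to W5.0 interaction 3439, Bowman W2.0 to W3.5 2370, and the steps of mnd1.a 1535 and 3689. The first interaction had 0 (edgeR, 2251 at an unadjusted p under 0.05, with 370 by DESeq2 and 23 by limma-voom over all groups) and Bowman W3.5 to W5.0 had 0 (edgeR, 3413 at an unadjusted p under 0.05, with 2572 and 1654). Without Bowman W3.5 replicates 2 and 4, W3.5 had 344, the first 2 interactions 25 and 430, and the steps of Bowman 3641 and 4018. The W3.5 to W5.0 interaction had 90 without prefix-separating genes, and the additive prefix model 458 for line and 933 for prefix. Of 18 list calls, 2 held with an estimated correlation, 18 under RLE and 17 with the lists as first written. At the strict threshold 7H was enriched also at W5.0 (odds ratio 1.48). The cause was not tested for any of these, except that a stricter threshold on the same test, or dropping genes that separate the prefixes, lowers a count by construction.

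With 1 library left out, counts ranged from 89 to 130 (W2.0), 265 to 2273 (W3.5), 4570 to 6919 (W5.0), 10 to 501, 136 to 293 and 930 to 2937 (interactions), 4042 to 7179 and 29 to 3523 (Bowman steps), 266 to 632 and 796 to 2741 (mnd1.a steps). Of the leave-outs of 291 called named results, 1987 kept the call, 369 lost it and 0 reversed, and all 291 kept it under RLE. Of 33 uncalled ones, 222 leave-outs were the same, 8 passed and 16 reversed. The reversals, as log2 ranges, were VRN-H1 (HORVU5Hr1G095630) from -0.0219 to 0.21, BM8 (HORVU2Hr1G063800) from -0.16 to 1.62, VRS1 (HORVU2Hr1G092290) from -3.20 to 3.92 and GI (HORVU3Hr1G021140) from -0.0347 to 0.12 at W2.0, GI from -0.0266 to 0.0494 at W3.5, INT-C (HORVU4Hr1G007040) from -0.36 to 0.0026 at W5.0, and the MND1 (HORVU7Hr1G113480) interaction from W2.0 to W5.0 from -0.28 to 0.31. The simulated recovery of 1.5-fold changes was 22.4% to 37.3% at the 3 stages.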

Other observations

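The comparisons here were picked out after the values were seen. At W5.0, where line and prefix coincide, a cytochrome P450 gene and an alcohol dehydrogenase gene near each other on 1H were higher in mnd1.a than in Bowman. Cytochrome P450 gene HORVU1Hr1G007900 (1H from 17000119 to 17002317) measured 11.8 ± 5.23 CPM in mnd1.a against 0.106 ± 0.143 CPM in Bowman (SD, n = 4 each, log2 6.79 ± 1.42, edgeR adjusted p = 0.00232), and alcohol dehydrogenase HORVU1Hr1G007800 (from 16446297 to 16448141) 6.32 ± 2.63 against 0.0845 ± 0.169 CPM (log2 6.10 ± 1.16, edgeR adjusted p = 0.00109). An alpha-glucosidase (HORVU7Hr1G028010), an enzyme of starch and sugar breakdown, went the other way, at 0.319 ± 0.260 against 10.9 ± 2.22 CPM (log2 -5.07 ± 0.62, edgeR adjusted p = 2.02e-05). A hexosyltransferase (HORVU0Hr1G000650) and a disease resistance gene (HORVU7Hr1G117570) had no counts in mnd1.a at W5.0, at least 58.5-fold and 55.7-fold lower than in Bowman. By its gene number the resistance gene falls among genes of the 7H segment around MND1, which may be donor chromosome. Its difference cannot therefore be ascribed to the allele.

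Single genes of other kinds also differed at W5.0. Expansin A1 (HORVU6Hr1G075970), which loosens cell walls, was at 176 against 99.1 CPM (log2 0.83 ± 0.19, edgeR adjusted p = 0.00306), a gibberellin-regulated protein (HORVU7Hr1G042390) had a log2 fold change of 0.97 ± 0.24, and a xyloglucan endotransglucosylase (HORVU7Hr1G012600) 1.15 ± 0.28. Trehalose phosphate synthase (HORVU0Hr1G028350), which makes a sugar signal, was lower, with a log2 fold change of -2.25 ± 0.42 (edgeR adjusted p = 0.00104), and DnaJ chaperone gene HORVU6Hr1G067130 was lower with -1.39 ± 0.14. The fatty acid oxidation complex was an enriched annotation family among lower genes at W5.0, with 7 of 11.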
